A study of Mus musculus with 15 samples.

How the data were processed

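RNA-seq was read in 11 mouse libraries (C57BL/6) and Pax5 ChIP-seq in 4. Per the labels, plasmablasts were cultured with lipopolysaccharide for 4 days and sorted, plasma cells were enriched and sorted from bone marrow, and chromatin came from cultured activated B cells or plasmablasts mixed with chicken DT40 cells. Groups were taken from the titles: control (Igh(+/+)) and IghPax5 (Igh(Pax5/+)) plasmablasts with 3 libraries each, plasma cells with 2 and 3, and 4 ChIP groups of 1 library. The description fields of 2 ChIP libraries, control plasmablasts and IghPax5 activated B cells, name the other genotype; titles and genotype fields, which match each other, were used. No label says which libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

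For RNA-seq the authors deposited TPM, reads divided by gene length and scaled to the same total in every library, as 1 column of 14371 values per library. The submitters' processing notes name cutadapt, TopHat 1.4.1, Bowtie 1.0, Bowtie2, Subread 1.5.0 with featureCounts, DESeq2, DESeq, R 3.4.1, SAMtools 1.9, bedtools 2.7.21 and MACS, with build mm9, and give none of them a role. The annotation and the rule by which rows were kept are not given in the sources used here. The deposited TPM files hold no gene identifiers, and no name was guessed from row order. The levels of Pax5 and other named genes, the tests of fixed gene lists, the scaling without immunoglobulin genes and the test of bound genes among changed genes, all planned, were therefore not run, and the genotype labels were not checked by the level of Pax5. Row order was checked instead: libraries of one experiment correlated with Spearman coefficients of at least 0.963, and at most 0.082 after a shift by 1 row.

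TPM keep the ratio of reads to length, and for 14370 of the 14371 rows a length was found at which the values of all 11 libraries were whole reads (tolerance 1e-05 reads); TPM rebuilt from these reads differed from the deposited ones by a relative 3e-14 at most. On simulated data with known reads, 99.96% of rows came back exactly and library totals were off by at most 0.0473%. Reads per library in these rows were 8632287, 9297219 and 8602246 for control plasmablasts, 9588519, 8083682 and 11621618 for IghPax5 plasmablasts, 14829477 and 19871223 for control plasma cells, and 25780984, 15913816 and 25320660 for IghPax5 plasma cells. Reads within groups differed by far more than sampling noise (chi-square per gene of 2.67 to 14.8 in plasmablasts and 17.1 to 69.6 in plasma cells), so no library was treated as a second copy of another. This does not show that the libraries are biological replicates.

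What is called planned was fixed before the data were examined. The planned test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(TPM + 1) after dividing each library's TPM by a median-of-ratios factor. Genes with a mean of at least 1 TPM over the libraries compared were kept, and two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The interaction of cell type and genotype was fitted over all 11 libraries; plasmablasts and plasma cells differ in origin and experiment, so no difference between them was read except that of the genotype effects and, in the closing part, a difference of controls. Among genes past the threshold with separate groups and at least 5 TPM in the higher group, the 2 largest increases and 2 largest decreases are named per comparison, and for the interaction the 2 smallest adjusted p in each direction; the planned rule took more genes and excluded some by name, which needs identifiers.

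In simulated counts for these genes and depths (10 draws, 200 changed genes, dispersion 0.02), limma on log2 TPM recovered 24.1%, 84.3% and 99.7% of genes changed 1.5-fold, 2-fold and 4-fold in the plasmablast design and 20.8%, 87% and 100% in the plasma cell design. False genes made up 6.71% and 11.7% of its calls, above the nominal 5%, and 3.92% and 5.69% with limma-voom on reads. Other choices planned were other scalings, pseudocounts of 0.1 and 5, other filters on level, robust eBayes, a shared fit of all 11 libraries, a term for the 2 runs of plasma cell library numbers, and leaving out each library in turn; where this leaves 1 library in an arm, that library is assumed to vary like the others. Limma-voom on the recovered reads was added after the data were seen. Library-number runs come from the titles; no label calls them a batch.

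For ChIP-seq the authors deposited peak lists, 1 mouse (mm9) and 1 chicken (gal5) list per library, so peaks were called per library. The score column of the deposited lists is 0 in every line, so no peak height, p or stricter threshold could be used, and the planned naming of the highest-scoring peaks was not possible. The caller and its threshold are not given in the sources used here except for MACS among the tools of the processing notes. The number of reads per genome in the ChIP libraries is unknown. Overlap was counted with bedtools 2.31.1 at 1 base or more, with at least 50% of each peak as the alternative. Regions were merged over the libraries where peaks overlapped. Overlap by position alone was estimated from 5 rotations of the second list along its chromosomes. Exact (Clopper-Pearson) 95% intervals of shares cover counting error only. Counting peaks at least as wide as the pooled median of 428.5 bases was added after the data were seen. The overlap step was tested on simulated data. An annotation of mm9 was not used here, so no peak is tied to a gene, and coordinates are as in the files, counted from 1. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.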

Results

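The study followed mouse B-lineage cells. The transcription factor Pax5, which maintains the identity of B cells, is shut down in the usual course of plasma cell formation. Its level could not be read here. By design, an immunoglobulin heavy-chain allele that carries Pax5 keeps this factor on. Cells with this allele, Igh(Pax5/+), are called IghPax5 below, and cells with 2 unmodified alleles, Igh(+/+), are called controls. All cells also carried 1 Prdm1 allele with a GFP reporter; Prdm1 encodes Blimp1, a regulator that plasma cells need. RNA was sequenced from plasmablasts grown in culture for 4 days with lipopolysaccharide, a bacterial product that activates B cells, with 3 control and 3 IghPax5 libraries, and from plasma cells sorted from mouse bone marrow, with 2 control and 3 IghPax5 libraries. Chromatin bound by Pax5 was sequenced (ChIP-seq) from cultured activated B cells and cultured plasmablasts of both genotypes, with 1 library per group; activated B cells were the cells left after magnetic depletion of a 4-day culture and plasmablasts those enriched from one. Each ChIP sample also held cells of the chicken B cell line DT40, which gave every library chicken peaks from the same kind of cell.

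The RNA values covered 14371 table rows, each taken here as 1 gene. The files did not pair the rows with gene names, so genes are given by their row number and by count, level and direction. Plasmablast libraries held 8083682 to 11621618 reads in these rows, and plasma cell libraries held 14829477 to 25780984. Between 10380 and 10976 genes per library reached 1 TPM, a length-corrected abundance scaled to the same total in each library. In plasmablasts the first principal component, with 55.9% of the variance, separated the genotypes, and in plasma cells it held 68.9% and did the same. The second component of plasmablasts, with 19.3%, set control replicate 3 (19.5) and IghPax5 replicate 3 (9.28) apart from the other libraries (-10.6 to -4.62).

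The first comparison asked which transcripts differ between IghPax5 and control plasmablasts in culture. In IghPax5 plasmablasts 134 genes were at least 2-fold higher and 87 at least 2-fold lower than in controls, 221 of 10578 genes tested (limma, Benjamini-Hochberg adjusted p under 0.05). By the rule for named genes, the largest increase was in row 5327, from 9.27 ± 2.04 TPM (SD, n = 3) in controls to 610.5 ± 94.5 TPM (SD, n = 3), a log2 change of 5.84 (SE 0.168, limma adjusted p = 9.96e-07). Row 13914 followed, from 4.53 ± 1.48 to 70.5 ± 10.6 TPM (SD, n = 3 each), a log2 change of 3.66 (SE 0.162, limma adjusted p = 6.07e-06). Row 9225 showed the largest decrease, from 19.5 ± 14.3 to 0.747 ± 0.406 TPM (SD, n = 3 each), a log2 change of -3.41 (SE 0.376, limma adjusted p = 0.000581). Its control libraries stood at 12.4, 10.1 and 36.0 TPM, and its IghPax5 libraries rested on 1 to 3 reads each, so the log2 change moved with the pseudocount, from -4.49 at 0.1 to -1.97 at 5. Row 12141 was lower by a log2 change of -2.68 (SE 0.19, limma adjusted p = 5.84e-05), from 119.5 ± 19 to 18.7 ± 3.5 TPM (SD, n = 3 each).

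Without the 2-fold limit, 1486 plasmablast genes passed the test, 709 higher and 777 lower in IghPax5 cells. Their changes were small, with a median log2 change of 0.62 for the higher genes and -0.48 for the lower ones. The lower genes were the more abundant, with a median control level of 53.3 TPM against 18.6 TPM for the higher genes and 22.1 TPM for all genes tested. Together the lower genes made up 13.7% ± 0.139 of all TPM in controls and 9.90% ± 0.197 in IghPax5 cells, and the higher genes 4.49% ± 0.353 and 7.16% ± 0.106 (SD, n = 3 each). These genes were chosen by their difference between the same libraries, which fixes the direction of the sums and can narrow their SDs. At least 4-fold changes were found in 19 higher and 7 lower genes. The 3 libraries of one genotype lay apart from the 3 of the other for 96.0% of the genes that passed and for 29.7% of all genes tested, where chance gives 10%. The first share follows largely from the choice of genes, and the TPM were not rescaled for either share. On TPM without rescaling of the libraries the median log2 change of all genes moved from -0.01 to 0.05, and the split turned to 756 higher and 513 lower genes. The count fell to 931, 871 and 890 without IghPax5 replicate 1, IghPax5 replicate 2 or control replicate 2, and the 2-fold count was 111 with a pseudocount of 5 and 332 with limma-voom on reads.

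The second comparison put the same question to plasma cells from mice. In IghPax5 plasma cells 516 genes were at least 2-fold higher and 210 at least 2-fold lower than in controls, 726 of 10938 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The largest increase was again in row 5327, which stood at 0.39 ± 0.0492 TPM (SD, n = 2) in controls, on 2 and 3 reads, and at 798.8 ± 106 TPM (SD, n = 3) in IghPax5 cells, a log2 change of 9.20 (SE 0.181, limma adjusted p = 1.04e-06). Row 4170 rose from 0.180 ± 0.0781 TPM (SD, n = 2) to 130.2 ± 18 TPM (SD, n = 3), a log2 change of 6.82 (SE 0.183, limma adjusted p = 3.33e-06). The same gene rose in plasmablasts to 7.03 ± 1.01 TPM (SD, n = 3), with 2, 0 and 0 reads in the control libraries. With so few control reads the plasma cell log2 changes moved with the pseudocount, from 10.73 at 0.1 to 7.25 at 5 for row 5327 and from 8.93 to 4.73 for row 4170. The largest decreases were in row 3864, from 29.5 ± 1.39 TPM (SD, n = 2) to 1.66 ± 0.877 TPM (SD, n = 3), and row 5968, from 76.1 ± 3.3 TPM (SD, n = 2) to 7.63 ± 7.04 TPM (SD, n = 3). Their log2 changes were -3.51 (SE 0.231, limma adjusted p = 0.000134) and -3.39 (SE 0.493, limma adjusted p = 0.00421). Both stood at 0.412 TPM or less in every plasmablast library. The IghPax5 plasma cell libraries of row 5968 stood at 3.78, 3.35 and 15.75 TPM, and without replicate 3 its log2 change was -3.96.

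**Figure D1:**
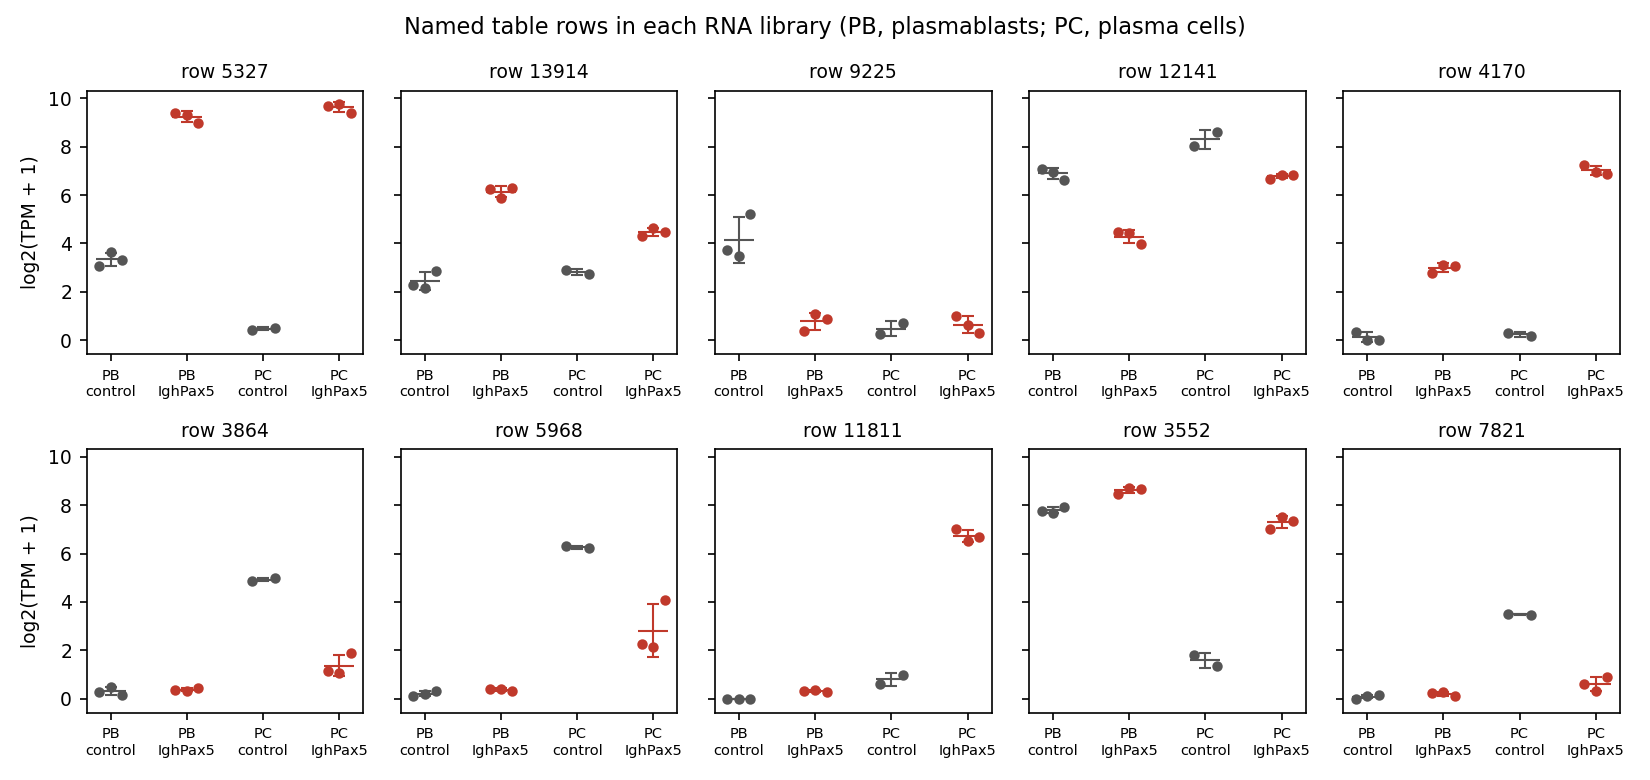
The panels plot log2(TPM + 1) of each named gene in the 11 RNA libraries, 1 point per library, with the mean and SD of each group as a bar; gray is control and red is IghPax5. Row 5327 rose in both cell types, to 610.5 TPM in plasmablasts and 798.8 TPM in plasma cells.

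Plasma cells held larger changes than plasmablasts. At least 4-fold changes were found in 158 higher and 22 lower genes, and 15 genes were at least 16-fold higher against 1 in plasmablasts. From below 1 TPM in controls, 46 genes rose to 5 TPM or more in IghPax5 plasma cells, against 3 in plasmablasts, and 5 fell from at least 5 TPM to below 1 TPM, against 2 in plasmablasts. Without the 2-fold limit 1530 genes passed, 933 higher and 597 lower, and on TPM without rescaling 750 were higher and 644 lower. The higher genes went from 4.93% ± 0.332 of all TPM (SD, n = 2) to 11.6% ± 0.0304 (SD, n = 3), and the lower genes from 9.93% ± 0.859 (SD, n = 2) to 4.12% ± 0.399 (SD, n = 3). As in plasmablasts, the choice of genes fixed the direction of these sums and can narrow their SDs. Every gene that passed had 2 control libraries apart from the 3 IghPax5 libraries, as had 43.8% of all genes tested, where chance gives 20%. Here too the choice of genes favors separation, and the TPM were not rescaled. Plasma cell libraries carried numbers from 2 separate runs, each with both genotypes, and the second principal component (18.4% of the variance) separated these runs. The genotype effects computed within each run, from separate libraries, had the same sign for 76.4% of all tested genes and correlated with r = 0.856 and rho = 0.743 across genes, which are not independent replicates. With the run as a term 2772 genes passed, 1444 higher and 1328 lower, among them all 1530. The count fell to 751, 837, 953 and 883 without control replicate 1, IghPax5 replicate 1, IghPax5 replicate 2 or control replicate 2, the 2-fold count to 413 with a pseudocount of 5, and the test called 11.7% false genes among its calls in simulated plasma cell data, above its nominal 5%.

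The genotype effects of both cell types were then set side by side; these comparisons share no library. Of 10168 genes tested in both, 563 passed in both, and 542 of these (96.3%, exact 95% confidence interval 94.4% to 97.7%) changed in the same direction. The interval treats genes as independent, which they are not, so it covers counting error only. Genes higher in both numbered 349 where independent lists would share 52.8, and genes lower in both numbered 193 where 37.2 would be shared. Over all 10168 genes the effects correlated with r = 0.586 and rho = 0.47 across genes. Opposite directions were found for 5 genes that rose in plasmablasts and fell in plasma cells and for 16 genes that did the reverse.

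**Figure D2:**
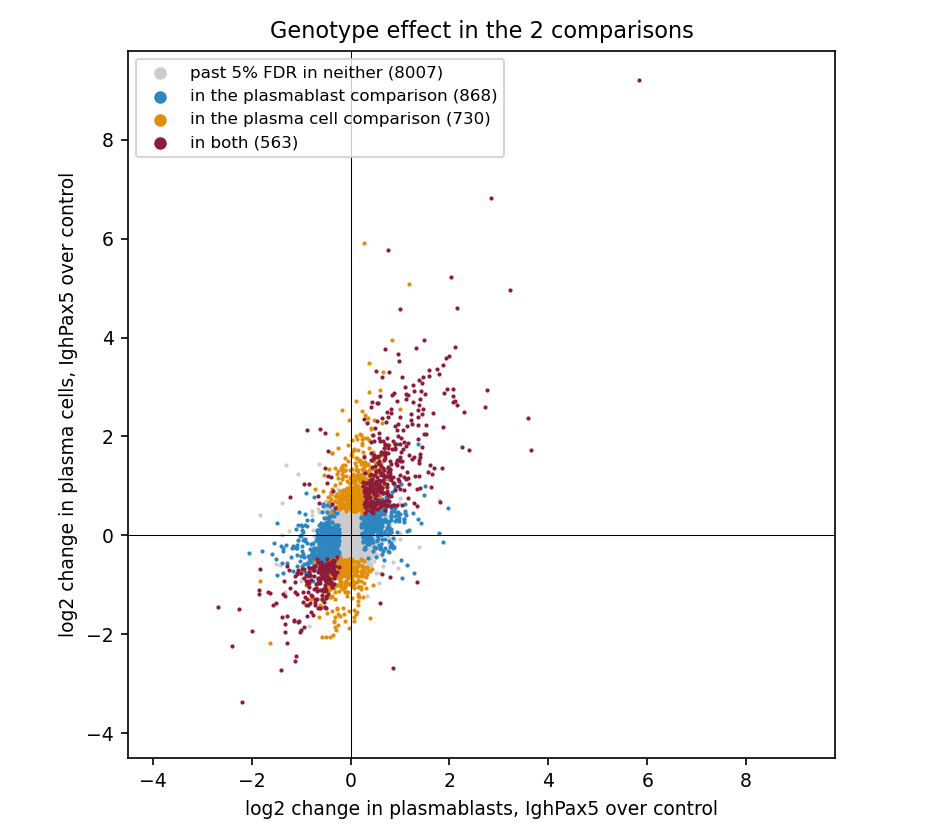
Each point is 1 of 10168 genes tested in both comparisons, with its log2 change (IghPax5 over control) in plasmablasts on the x axis and in plasma cells on the y axis, colored by the comparison in which it passed a false discovery rate of 5%. Of the 563 genes that passed in both, 542 lie in the quadrants of equal sign.

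The difference of the genotype effects was tested as an interaction over all 11 libraries. It passed for 789 of 10945 genes (limma, Benjamini-Hochberg adjusted p under 0.05), with 514 effects more positive and 275 more negative in plasma cells. The fit used 1 spread per gene for both cell types. Genotype counts taken from this shared fit moved from 1530 to 2413 in plasma cells and from 1486 to 1004 in plasmablasts. The shared fit also changed the scaling and the genes tested, and the causes of the moves were not tested. The 789 rest on the same fit. No term for the library-number runs was used, and false calls of the interaction were not simulated. The smallest adjusted p in the first set was shared by row 11811 and row 3552. Row 11811 was listed at 0 in the 3 control plasmablast libraries, at 0.237 ± 0.0381 TPM (SD, n = 3), on 2 reads per library, in IghPax5 plasmablasts, at 0.751 ± 0.339 TPM (SD, n = 2) in control plasma cells and at 107 ± 19.7 TPM (SD, n = 3) in IghPax5 plasma cells. Row 3552 stood at 222.7 ± 19.3 TPM in control plasmablasts and 395.1 ± 35.6 TPM in IghPax5 plasmablasts (SD, n = 3 each). It stood at 2.04 ± 0.658 TPM (SD, n = 2) in control plasma cells and at 157.7 ± 26.6 TPM (SD, n = 3) in IghPax5 plasma cells. In the second set, row 3864 and row 7821 had the smallest adjusted p; row 7821 stood at 10.2 ± 0.187 TPM (SD, n = 2) in control and 0.542 ± 0.304 TPM (SD, n = 3) in IghPax5 plasma cells, and at no more than 2 reads in any plasmablast library. Of the 514 genes, 133 had risen in both comparisons, 202 had risen in plasma cells without passing in plasmablasts and 80 had risen in plasma cells without being tested in plasmablasts. A further 52 had fallen in plasmablasts without passing in plasma cells, and 16 had fallen in plasmablasts and risen in plasma cells. Of the 275 genes, 123 had fallen in plasma cells without passing in plasmablasts, 52 had fallen in plasma cells without being tested in plasmablasts, 37 had risen in plasmablasts without passing in plasma cells and 18 had fallen in both. The 52 untested genes had a mean below 1 TPM in plasmablasts, where a fall could hardly be seen. On TPM without rescaling the median interaction of all genes moved to -0.12, and the split became 357 more positive and 345 more negative.

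The ChIP-seq comparison asked where Pax5 sits on chromatin in activated B cells and in plasmablasts, both taken from 4-day cultures. In controls, 9934 mouse peaks were listed for activated B cells and 1618 for plasmablasts, which is 16.3% as many. In IghPax5 cells the numbers were 17907 and 20481, so plasmablasts held 114.4% as many as activated B cells. IghPax5 activated B cells held 180.3% of the peaks of control activated B cells. With 1 library per group these numbers have no replicate error and no test was made. The genotype of 2 of the libraries, control plasmablasts and IghPax5 activated B cells, was taken from titles and genotype fields, and their description fields name the other genotype. Chicken peaks ran from 870 to 1046 in 3 libraries and reached 3231 in control plasmablasts. Control plasmablasts therefore held 0.501 mouse peaks per chicken peak, control activated B cells 9.50, IghPax5 activated B cells 20.6 and IghPax5 plasmablasts 21.1. The order of the IghPax5 libraries turned when peaks of at least 428.5 bases were counted, the median width of all mouse peaks, with plasmablasts then at 82.5% of activated B cells.

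**Figure D3:**
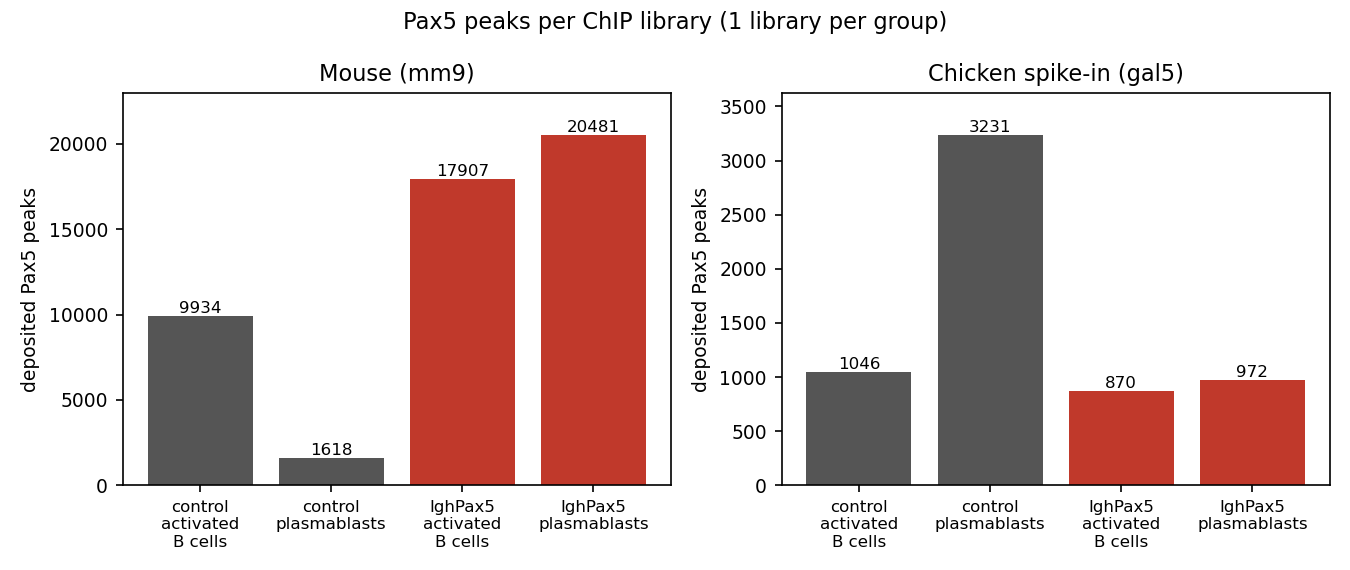
Bars give the number of deposited Pax5 peaks in each of the 4 ChIP libraries, mouse peaks on the left and chicken spike-in peaks on the right, on axes that start at 0; gray is control and red is IghPax5. Control plasmablasts have the lowest mouse count, 1618, and the highest chicken count, 3231.

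Nearly all control plasmablast peaks were also listed in the other libraries. Of the control plasmablast peaks, 96.7% overlapped a peak of control activated B cells by at least 1 base and 98.2% a peak of IghPax5 plasmablasts. In the other direction, 15.5% of control activated B cell peaks (exact 95% confidence interval 14.8% to 16.3%, counting error only) were found in control plasmablasts and 87.9% (87.3% to 88.6%) in IghPax5 plasmablasts. Placing the second set at shifted positions on the same chromosomes gave overlaps of 0.0463% and 0.769%. The 8391 control activated B cell peaks without a counterpart in control plasmablasts had a median width of 377 bases, against 554 bases for the 1543 with one, and 7212 of the 8391 (85.9%) were found in IghPax5 plasmablasts. IghPax5 activated B cells and IghPax5 plasmablasts shared more of their merged regions, 61.7%, than any other pair. Unequal list lengths cap this share, and these lists were the longest, with 17907 and 20481 peaks. As a share of the shorter list the order differed: 80.9% of IghPax5 activated B cell peaks were found in IghPax5 plasmablasts. Of control activated B cell peaks, 96.4% were found in IghPax5 activated B cells. The overlap counts depended on the rule for control plasmablasts, whose peaks had a median width of 274 bases: with at least 50% of each peak required, 40.1% of them were found in IghPax5 plasmablasts and 8.31% of control activated B cell peaks were found in them.

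Of 23578 merged mouse regions, 1514 were present in all 4 libraries and 6872 in all but control plasmablasts. A further 5994 were shared by the IghPax5 libraries without either control, and 9 were listed in control plasmablasts alone. Peaks of IghPax5 activated B cells without a counterpart in control activated B cells numbered 8522 (47.6%) and were narrower, with a median of 405.5 bases against 592 bases for the others. Of these, 71.4% were found in IghPax5 plasmablasts, against 89.6% of the peaks that control activated B cells also held. In IghPax5 plasmablasts 5389 peaks (26.3%) lay in neither activated B cell library, with a median width of 297 bases against 453 bases for the rest.

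**Figure D4:**
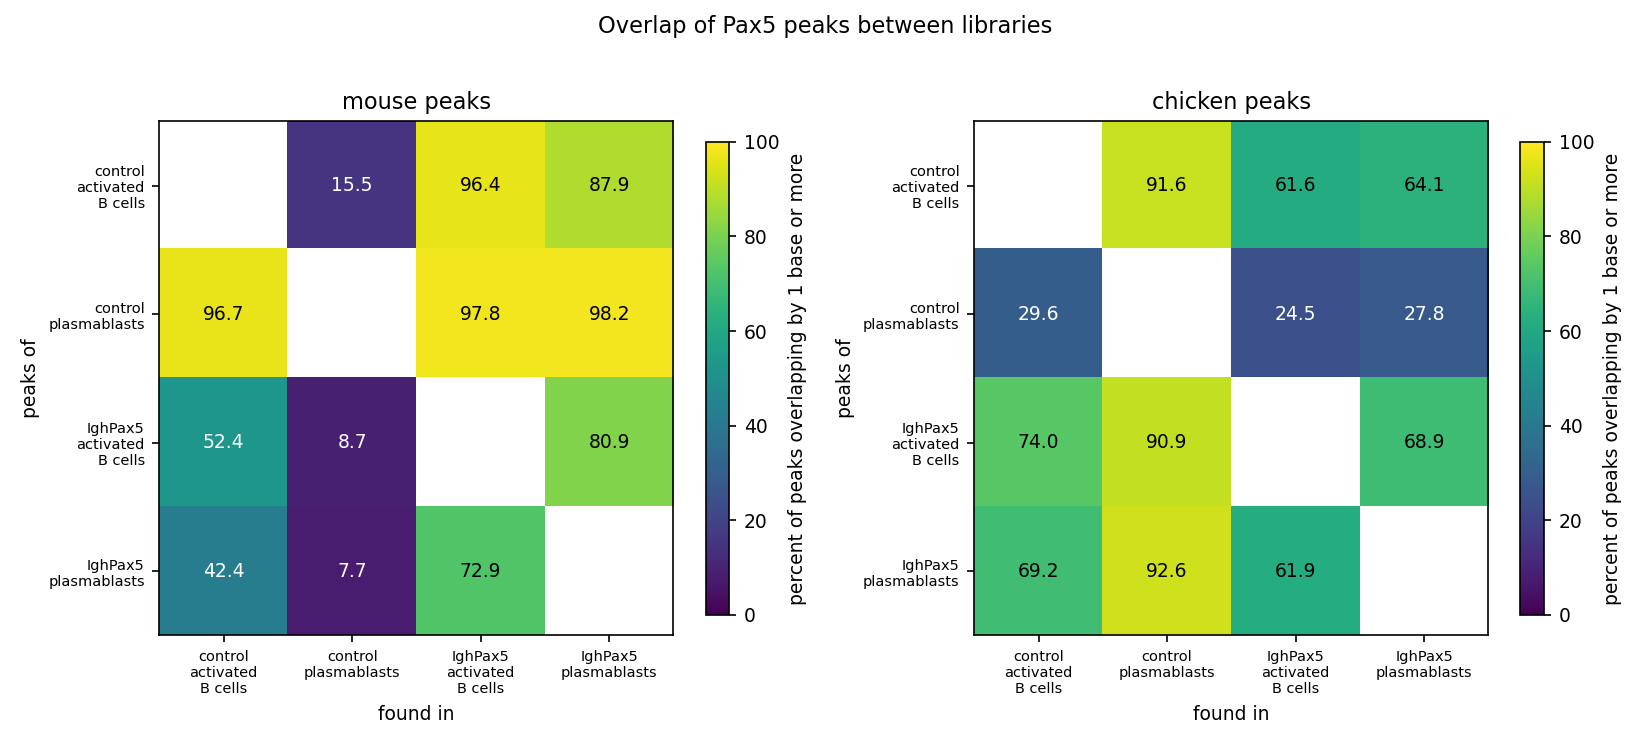
Each cell gives the percent of the peaks of the library in its line that overlap a peak of the library in its column by at least 1 base, for mouse peaks on the left and chicken peaks on the right. Control plasmablasts held 15.5% of the mouse peaks of control activated B cells but 91.6% of their chicken peaks. Their list was the shortest in mouse, with 1618 peaks, and the longest in chicken, with 3231 peaks, which bears on both shares.

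In the chicken genome, where the same cell line was in every sample, control plasmablasts held 91.6%, 90.9% and 92.6% of the peaks of control activated B cells, IghPax5 activated B cells and IghPax5 plasmablasts. Their chicken list was the longest, with 3231 peaks, and a longer list raises such shares. In the other direction 29.65%, 24.5% and 27.8% of its peaks were found in these libraries. Among those other 3 libraries, pairs shared 61.6% to 74.0% of their chicken peaks. In mouse the same pairs ran more widely, from 42.4% to 96.4%. The lowest was for IghPax5 plasmablast peaks found in control activated B cells. The highest was for control activated B cell peaks found in IghPax5 activated B cells, and the reverse of that pair was 52.4%.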

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

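The tests of reads and of exchanged labels in the ChIP libraries, the count of wide peaks and limma-voom were chosen only after the data were seen; the others were fixed before their results were seen. A test of the difference of genotype effects (limma interaction, Benjamini-Hochberg adjusted p under 0.05) passed for 514 genes with a more positive and 275 genes with a more negative effect in plasma cells than in plasmablasts. It used a spread shared by both cell types and no term for the library-number runs. The log2 effect in plasma cells minus that in plasmablasts was 5.75 for row 11811 (limma adjusted p = 1.68e-07), 5.02 for row 3552 (limma adjusted p = 1.68e-07), -3.58 for row 3864 (limma adjusted p = 1.05e-05) and -3.00 for row 7821 (limma adjusted p = 1.43e-05). The fitted value of row 11811 is no bound on a fold, since it is listed at 0 in all control plasmablast libraries. Rows 3864 and 7821 had at most 4 and 2 reads in any plasmablast library, so a fall there could not have been measured. Their values set the plasma cell fall against a floor and do not show a measured difference of effects.

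More genes changed at least 2-fold in plasma cells (726) than in plasmablasts (221). Deeper plasma cell libraries do not account for this: thinned to 8083682 reads, the depth of the shallowest plasmablast library, plasma cells still gave a median of 725 genes (710 to 740 over 20 draws). Nor does the scaling, since the lowest ratio of the 2 counts over 3 scalings was 2.96. With 2 controls against 3, as in plasma cells, plasmablasts gave 221, 223 and 259 genes (without control replicate 1, 2 or 3), and limma-voom, which made fewer false calls in simulated data, gave 862 genes in plasma cells and 332 in plasmablasts. Cell type and culture against mouse were not separated by these tests and stay open, so a biological difference between the cell types is untested. For the plasmablast count of 1486 genes without the 2-fold limit, the 6 libraries were split in 10 ways. Only the real split gave as many, 1 of 10, and the highest of the others gave 0. Each other split held both genotypes in both arms, so the genotype difference entered its spread. Their 0 therefore does not measure chance calls. With 10 splits the share cannot fall under 0.1.

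Control plasmablasts held 16.3% of the mouse peaks of control activated B cells and IghPax5 plasmablasts 114.4% of those of IghPax5 activated B cells, a difference that was not tested, with 1 library per group; the second value was 102.4% per chicken peak and 82.5% with wide peaks alone, so its direction is open. The control plasmablast library also held 3.09 times as many chicken peaks as the next library. Fewer mouse reads in that library may account for both, but less Pax5-bound mouse DNA would also leave a larger share of chicken reads, so these cannot be told apart here. The reads per genome are unknown and would show a larger chicken share under either explanation. Repression of Pax5 in control plasmablasts, which the design addresses, stays open as well. If the description fields were right, both activated B cell libraries would be 1 condition, and both plasmablast libraries would be 1 condition too. The activated B cell libraries shared 51.5% of their merged mouse peaks, the plasmablast libraries 7.82% and the libraries titled as IghPax5 61.7%. Unequal list lengths cap these shares (9934 and 17907, 1618 and 20481, 17907 and 20481 peaks), so their order cannot decide about the labels. The plasmablast libraries held 0.501 and 21.1 mouse peaks per chicken peak, far apart for 1 condition. With 1 library per group these values have no spread, so an exchange is not excluded.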

How the results depend on the processing

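Limma-voom on reads, the pooled-width rule for peaks and the recomputing of the shared direction were chosen after the data were seen. All 195 values of named genes under the alternatives kept their direction and passed the threshold; row 7821 had no value with a minimum of 5 TPM. These genes were chosen for large changes or small adjusted p in the same libraries, which makes such persistence likely. The interaction values of rows 3864 and 7821 set a plasma cell fall against a floor in plasmablasts. Sizes of the named changes moved with the pseudocount and with limma-voom. Over the settings that kept all libraries, log2 changes stayed within 5.38 to 5.97 for row 5327 and -2.77 to -2.45 for row 12141 in plasmablasts, but ran from 2.94 to 3.93 for row 13914 and from -4.49 to -1.97 for row 9225. In plasma cells they ran from 7.25 to 10.81 for row 5327, from 4.73 to 9.41 for row 4170, from -4.12 to -2.34 for row 3864 and from -3.60 to -2.77 for row 5968. The interaction ran from 4.31 to 5.83 for row 11811, from 3.86 to 5.63 for row 3552, from -4.36 to -2.40 for row 3864 and from -4.97 to -1.50 for row 7821. The 1486 plasmablast genes ranged from 1004 to 1669 over 9 settings and from 871 (without IghPax5 replicate 2) to 2113 (without control replicate 3) with 1 library left out, with 931 without IghPax5 replicate 1 and 890 without control replicate 2. Their 2-fold count of 221 was 111 with a pseudocount of 5 and 332 with limma-voom, and 211 to 259 with 1 library left out. The 1530 plasma cell genes became 2413 with all 11 libraries in one fit (plasmablasts: 1004) and 2772 with a term for the library-number run (the causes were not tested), and ranged from 751 (without control replicate 1) to 1648 (without IghPax5 replicate 3) with 1 library left out, with 837 and 953 without IghPax5 replicates 1 and 2 and 883 without control replicate 2. Their 2-fold count of 726 was 413 with a pseudocount of 5, which shrinks the changes of low genes, and 639 to 798 with 1 library left out. The interaction ranged from 543 to 916 genes over 8 settings and from 545 to 953 with 1 library left out, and the share of genes with the same direction from 94.8% to 97.2% over all of these. Without rescaling, the median log2 change of all genes moved to 0.05 in plasmablasts, -0.08 in plasma cells and -0.12 in the interaction.

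Peak results moved with every alternative. Per chicken peak, control plasmablasts had 5.27% of the mouse peaks of control activated B cells, IghPax5 plasmablasts 102.4% of those of IghPax5 activated B cells, IghPax5 activated B cells 216.7% of control activated B cells, and IghPax5 plasmablasts 4208% of control plasmablasts, against 16.3%, 114.4%, 180.3% and 1266% in numbers of peaks. With wide peaks alone these were 4.99%, 82.5% (the direction turned; the cause was not tested), 262.9% and 4348%. With 50% of each peak required, the shares of control activated B cell peaks found in control and in IghPax5 plasmablasts were 8.31% and 78.7%, that of IghPax5 activated B cell peaks found in IghPax5 plasmablasts 75.2%, and that of control plasmablast peaks found in IghPax5 plasmablasts 40.1%; with wide peaks alone they were 4.78%, 84.3%, 66.5% and 91.6%. For these shares the cause was not tested.

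Scaling without immunoglobulin genes, the Pax5 and gene list results, the bound-gene test and a stricter peak score were not run, since the files hold no gene identifiers and no scores. No paired analysis was possible because the groups share no replicate numbers in the labels; the term for the library-number run pairs no libraries. At the depth of the plasmablast libraries, 24.1% of simulated 1.5-fold changes were recovered with an assumed dispersion of 0.02; the share in the real data is not known.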

Other observations

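The values of genes without a read, of genes at low level, of the widest peaks and of chromosome X were chosen after the data were seen; the tests on neighbouring genes and on control differences were fixed before their results, though neighbours had been seen to change together. Control plasmablasts left more genes without a read than IghPax5 plasmablasts. Thinned to 8083682 reads, the 3 control libraries had 1153, 1229 and 1294 genes without a read and the 3 IghPax5 libraries 732, 701 and 912 (means 1225 ± 70.7 and 782 ± 114, SD, n = 3 each; an exact permutation test of 3 against 3 cannot go below p = 0.1). Among the 3730 plasmablast genes below a mean of 1 TPM, which the tests left out, all IghPax5 libraries were above all controls for 594 (15.9%) and below them for 121 (3.24%). Without ties, chance would give 5% each way. Among the 3425 such plasma cell genes the shares were 16.8% above and 11.7% below, where chance without ties would give 10% each way. Libraries tied at 0 reads cannot be separated, which lowers the chance shares by an amount not computed here. A share below or near these limits therefore shows neither depletion nor chance. The TPM were not rescaled for these shares. In plasma cells the thinned numbers were 933 and 976 in controls and 1008, 391 and 949 in IghPax5 libraries, so IghPax5 replicate 2 stood apart.

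Genes that sit next to each other in the table changed together more often than chance placed them. Pairs of adjacent genes that both changed at least 2-fold in the same direction numbered 15 in plasmablasts, 8.31 times the 1.81 obtained by permuting calls among genes of similar level, and 66 in plasma cells, 3.02 times the 21.9 obtained (permutation p = 1e-04 for each, the smallest that 10000 permutations can give). Similar levels of neighbours therefore do not account for the pairs. The order of the table is not stated, so whether neighbours lie close in the genome, are related in sequence or share reads was not tested, and no biological explanation was tested.

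One hypothesis was that IghPax5 plasma cells keep part of the expression of an earlier stage. If so, genes higher in control plasmablasts than in control plasma cells would be higher in IghPax5 than in control plasma cells. With a different control plasma cell library in each difference, the correlation across genes was 0.202 one way and 0.207 the other, above the limit of 0.1 set beforehand. Of the 385 genes at least 4-fold higher in control plasmablasts in the first arrangement, 76.6% were higher in IghPax5 plasma cells, against 48.5% of all genes, and of the 452 genes at least 4-fold lower, 31.4% were higher. The hypothesis predicts these directions, and they held for a part of the genes. Both differences subtract control plasma cells, so a trait common to the control plasma cell libraries can also raise r. The limit of 0.1 does not allow for that, so passing it does not decide the hypothesis. Culture against mouse is confounded with stage in these controls, and r is small. Genes are not independent replicates.

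The widest mouse peak of each library was looked at after its values were seen. In both control libraries the widest peak lay on chromosome 6 of mm9, from 113021630 to 113027608 in activated B cells (5979 bases) and from 113021601 to 113027391 in plasmablasts (5791 bases), while the IghPax5 libraries held peaks of 1653 and 1982 bases at its right end. In both IghPax5 libraries the widest peak lay on chromosome 17, at 39979920 to 39985839 and 39979899 to 39985844, a stretch that control activated B cells covered with peaks of 3965, 375 and 1442 bases and control plasmablasts with 4 peaks of up to 2303 bases, so the difference there lies at least partly in where the stretch was split. With 1 library per group no difference of these peaks between genotypes was tested. No input library or annotation of repeats was used, so whether these wide peaks reflect Pax5 binding was not tested. Chromosome X held 1.24% to 1.61% of the peaks of each library, although its last peak end makes up 6.32% of the sum over chromosomes.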
